A study of Homo sapiens with 9 samples.

How the data were processed

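RNA from HK-2 cells was sequenced in 9 libraries, 3 per group: control, PM2.5, and lactoferrin followed by PM2.5. Groups and replicate numbers were taken from the sample labels. Per the submitters' processing notes, which list tools without their order or settings, the work used CASAVA, FastQC, MultiQC, Trimmomatic 0.38, HISAT2 2.1.0, featureCounts 1.6.0 and DESeq2 1.22.1 with genome build GRCh38. The annotation release, the strand setting and whether reads or fragments were counted are not given in the sources used here, so overlapping and antisense genes, and near-identical copies, could not be told apart by strand or by read assignment.

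The deposited values were FPKM, 1 file per sample, each listing 58884 Ensembl gene identifiers. The unit was inferred from the values. When a value was multiplied by the gene's union exon length in GENCODE v29 (58611 identifiers matched), between 86.0% and 87.2% of the low values per library (those of at most 200 reads or fragments) were whole multiples of 1 step within a tolerance of 0.05. The step gave 15313477 to 18820207 assigned reads or fragments per library, and the sum of the rebuilt values differed from that total by 0.14% to 0.41%. Gene symbols were found for 42371 identifiers, and coordinates are those of GENCODE v29 on GRCh38. The mitochondrial share of the rebuilt values was between 5.79% and 9.33%.

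Before the data were examined, the design had been written for raw counts, with a quasi-likelihood test for counts as the main test. The files held FPKM, so that test was not used here, and the test was limma on log values. FPKM were divided by a trimmed mean of M values factor (0.942 to 1.036), and log2(FPKM + 0.5) was modelled in limma 3.58.1 (R 4.3.3) with 3 group means and eBayes with trend and robust options. Benjamini-Hochberg adjustment was over the 14454 genes with an FPKM of at least 0.5 in at least 3 libraries. All 9 libraries entered 1 fit, so that the groups shared an estimate of the spread. Fold changes are on the log2(FPKM + 0.5) scale with their standard errors.

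Gene lists (35) and focus genes (38) were fixed before the data were examined. The 33 lists with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry. Immune cell markers and distal and collecting duct markers had 3 tested genes each, and 18 and 17 of their genes stayed below 1 FPKM in every library. Other marker lists were tested in part: 10 of 26 proximal tubule, 8 of 36 squamous and keratinocyte, and 5 of 22 fibroblast and endothelial markers. Genes named for each comparison were the 8 largest increases and 8 largest decreases among called genes with a symbol, a mean log2 CPM of at least 2 and no overlap between groups. They further included the 2 members of each called list with the smallest adjusted p, the focus genes, and the genes changed in opposite directions by PM2.5 and by lactoferrin. Some genes that this rule selects are not reported here. The focus genes IL1B, NLRP3, CDH1 and LTF were below the filter, and 34 were tested. Of these 21 rose and 5 fell with PM2.5, 0 rose and 1 fell with lactoferrin plus PM2.5 against PM2.5, and 19 rose and 5 fell with lactoferrin plus PM2.5 against control.

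The analysis was tested on simulated libraries with 200 changed genes, drawn with a dispersion of 0.0081. This was the median over well-covered genes of the replicates and was used for every gene. No library-wide differences were simulated, so the shares recovered may overstate those in the real libraries. For PM2.5 against control 4% of genes changed 1.25-fold, 54% of 1.5-fold, 86% of 2-fold and 92% of 4-fold changes were recovered, with 14305 genes tested. For lactoferrin plus PM2.5 against PM2.5 the shares were 4%, 56%, 76% and 94% (14327 genes), and for lactoferrin plus PM2.5 against control 10%, 70%, 94% and 100% (14325 genes). Between 7 and 10 unchanged genes were called. Unchanged groups sharing libraries were simulated in 50 draws from the residuals. Alternatives covered scaling, filters, pseudocounts, limma-voom on rebuilt fragments, a replicate block, library weights, removal of a trend on transcript length and GC content, and leaving out each library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.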

Results

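RNA was sequenced from HK-2 cells, an immortalised line of human renal proximal tubule epithelial cells. The 9 libraries formed 3 groups of 3: untreated control cells, cells exposed to fine airborne particulate matter (PM2.5), and cells pretreated with lactoferrin, an iron-binding glycoprotein of milk and neutrophil granules, before PM2.5. The labels give 24 h of exposure for the PM2.5 group, and 6 h of lactoferrin followed by 18 h of PM2.5 for the pretreated group, which are different times in PM2.5. The series text gives 18 h for pretreated cells and no time for the PM2.5 group. Its doses are 1 mg/ml of PM2.5 and 40 mg/ml of lactoferrin, and these units could not be checked. The results hold for the doses used, whichever unit is right. The deposited FPKM values corresponded to between 15313477 and 18820207 reads or fragments assigned to genes per library, and 14454 genes were tested. The labels do not say whether the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

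The first principal component of the log2 values held 54.4% of the variance and parted the 3 control libraries from the 6 exposed ones. The second component (13.6%) set lactoferrin replicate 1 apart, at 38.1 against 7.9 and -7.1 for the other libraries of its group. The third (8.8%) set control replicate 3 apart, at 27.0. Each group's replicate pairs differed beyond sampling noise, with a chi-square per gene between 2.54 and 58.1. This cannot tell separate cultures from separate libraries of 1 culture. Each library was counted as 1 replicate.

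The first comparison asked how exposure to PM2.5 changed the transcriptome. Of 23 NRF2 targets 21 rose (adjusted p = 0.135 for the list with an estimated correlation). HMOX1 (heme oxygenase 1, ENSG00000100292, GRCh38 chromosome 22, 35380361 to 35394214, plus strand) went from 49.7 ± 6.33 FPKM in control to 832 ± 75.7 FPKM (SD, n = 3 each), a log2 fold change of 4.01 ± 0.13 (SE). Of 23 ATF4 targets 19 rose (adjusted p = 0.135 for the list with an estimated correlation), among them GDF15 (log2 fold change 2.35 ± 0.15) and TRIB3 (2.11 ± 0.15). Of 24 G2 and M phase genes 20 fell (adjusted p = 0.15 for the list with an estimated correlation), among them KIF20A, a mitotic kinesin (16.0 ± 0.818 to 6.58 ± 0.562 FPKM, log2 fold change -1.27 ± 0.10). In total 2702 genes were higher and 2374 lower at an adjusted p under 0.05 (limma, Benjamini-Hochberg), and 463 and 523 of them changed by at least 2-fold.

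On the log2(FPKM + 0.5) scale, the largest increases among the genes that the naming rule selects were those of ANGPTL4, an inhibitor of lipoprotein lipase (log2 fold change 4.33 ± 0.12), and MMP1, interstitial collagenase (4.32 ± 0.10). HMOX1 came next, followed by the vacuolar ATPase subunit gene ATP6V0D2 (3.98 ± 0.14), the thrombomodulin gene THBD (3.88 ± 0.22), CSF2, which encodes GM-CSF (3.79 ± 0.14), VGF (3.52 ± 0.19) and the transporter gene SLC16A6 (2.92 ± 0.12). The largest decrease on that scale was that of IGFBP3, a carrier of insulin-like growth factors, from 53.9 ± 2.33 to 2.19 ± 0.169 FPKM (-4.38 ± 0.08). NCKAP5 (-3.53 ± 0.16), LINC02274 (-3.32 ± 0.31), ID3 (-3.24 ± 0.18), FILIP1L (-3.14 ± 0.27), THBS1 (-3.08 ± 0.19), CRABP2 (-2.93 ± 0.13) and FGFR2 (-2.74 ± 0.12) followed. The order depends on the 0.5 added: the mean FPKM of ATP6V0D2 went from 0.289 to 12.1 and that of ANGPTL4 from 1.32 to 37.2, and NCKAP5 went from 9.22 to 0.357. The adjusted p of these 16 genes lay between 1.31e-08 and 6.43e-05.

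**Figure D1:**
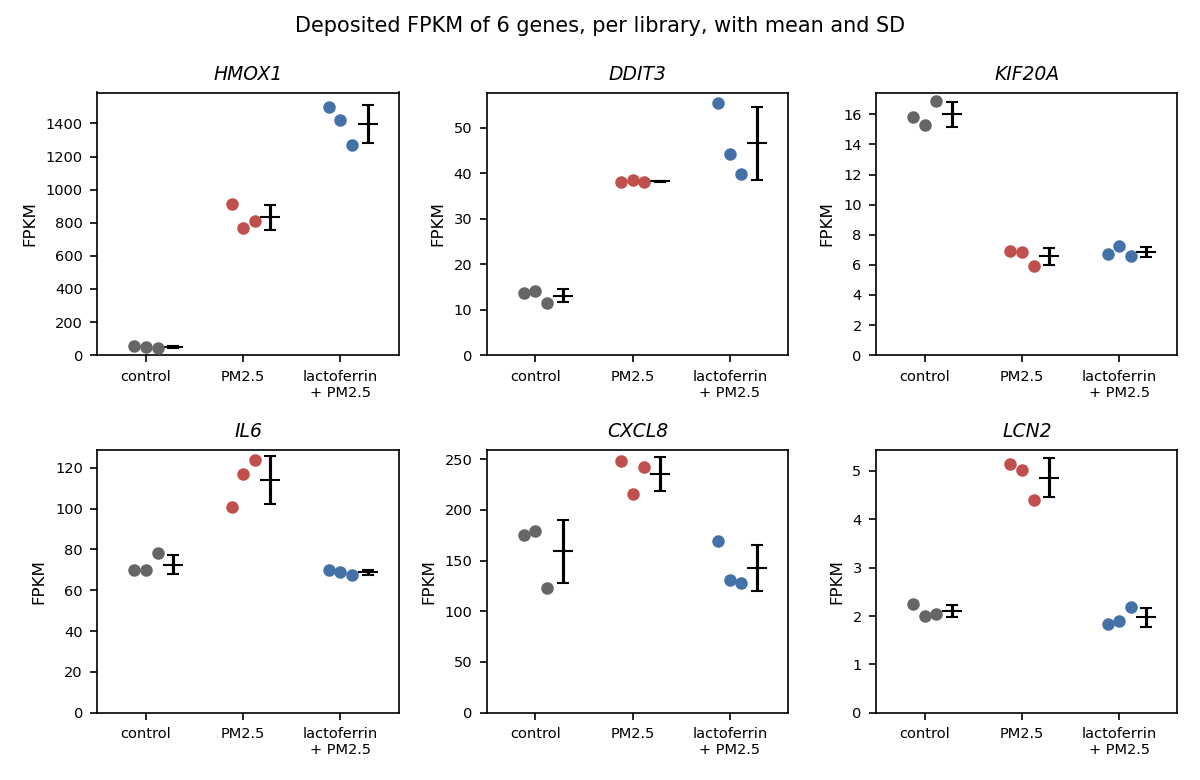
FPKM (linear axes from 0) of 6 genes in each of the 9 libraries, grouped as control, PM2.5 and lactoferrin plus PM2.5. Points are libraries and the bars beside them the group mean and SD (n = 3). The HMOX1 means were 49.7, 832 and 1400 FPKM, and the IL6 means 72.6, 114 and 68.9 FPKM.

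Of the 23 tested NRF2 targets, 21 rose (22 adjusted over the list alone) and their median log2 fold change was 1.03 (camera adjusted p = 2.64e-12; adjusted p = 0.135 with an estimated correlation). GCLM, a subunit of the enzyme that starts glutathione synthesis, rose by a log2 fold change of 1.37 ± 0.07, NQO1 by 2.17 ± 0.15 and the cystine transporter gene SLC7A11 by 1.62 ± 0.18. Of the 23 ATF4 targets 19 rose (19 adjusted over the list alone), with DDIT3, the transcription factor CHOP, going from 13.0 ± 1.39 to 38.2 ± 0.193 FPKM (camera adjusted p = 2.46e-10; adjusted p = 0.135 with an estimated correlation). In the unfolded protein response list 14 of 21 genes rose (15 adjusted over the list alone), HERPUD1 by 0.94 ± 0.09 and DNAJB9 by 0.82 ± 0.11 (camera adjusted p = 0.000118; adjusted p = 0.15 with an estimated correlation). The autophagy and lysosome list had 18 of 27 genes higher and 2 lower (18 and 2 adjusted over the list alone). It included the autophagy receptor gene SQSTM1 (1.87 ± 0.11) and the protease gene CTSL (1.90 ± 0.12), with a camera adjusted p = 1.09e-05 and an adjusted p = 0.135 with an estimated correlation. Heat shock genes had 5 of 20 higher and 1 lower (5 and 0 adjusted over the list alone), with HSPA1B at 1.34 ± 0.10 and HSPA6 at 2.32 ± 0.09 (camera adjusted p = 0.0118; adjusted p = 0.477 with an estimated correlation). HSPA1A and HSPA1B are near-identical copies, as HSPA6 is with a related pseudogene, so how reads were divided between them is uncertain.

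Of 22 EGFR ligands and MAPK feedback genes, 14 rose and 2 fell (14 and 4 adjusted over the list alone), with the ERK phosphatase gene DUSP6 at 2.09 ± 0.09 and DUSP5 at 1.64 ± 0.08 (camera adjusted p = 0.000118; adjusted p = 0.354 with an estimated correlation). Of 26 NF-kB targets and cytokines 12 rose and 3 fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.0115; adjusted p = 0.135 with an estimated correlation). CXCL2 rose by 1.45 ± 0.12, IL6 from 72.6 ± 4.68 to 114 ± 11.9 FPKM, CXCL8 from 159 ± 31.3 to 235 ± 17.0 FPKM, and LCN2, which encodes the kidney injury marker NGAL, from 2.1 ± 0.131 to 4.86 ± 0.395 FPKM. The complement and coagulation list had 7 of 16 higher and 3 lower (7 and 3 adjusted over the list alone), with PLAU, urokinase, at 1.53 ± 0.09 (camera adjusted p = 0.0127; adjusted p = 0.52 with an estimated correlation). Of 24 cholesterol synthesis genes 11 rose and 3 fell (12 and 3 adjusted over the list alone), with INSIG1 at 2.53 ± 0.07 and MSMO1 at 0.93 ± 0.09 (camera adjusted p = 0.0181; adjusted p = 0.15 with an estimated correlation). Of 18 genes of fatty acid synthesis and lipid droplets 10 rose and 2 fell (10 and 4 adjusted over the list alone), with G0S2 at 2.73 ± 0.18 and the lipid droplet coat gene PLIN2 at 1.09 ± 0.10 (camera adjusted p = 0.0482; adjusted p = 0.253 with an estimated correlation). The call of the fatty acid synthesis and lipid droplets list ended without control replicate 1 (adjusted p = 0.073), 2 (0.058) or 3 (0.0676), PM2.5 replicate 2 (0.0592) or lactoferrin replicate 3 (0.0509). It also ended under the stricter filter (0.0594), after the length and GC trend was removed (0.073) and without control replicate 3 and lactoferrin replicate 1 together (0.0594).

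Iron handling had 10 of 18 genes higher and 2 lower (11 and 2 adjusted over the list alone), with the ferrireductase gene STEAP3 at 1.00 ± 0.11 and the iron transporter gene SLC11A2 at 0.64 ± 0.08 (camera adjusted p = 0.0181; adjusted p = 0.15 with an estimated correlation). The ferritin heavy chain gene FTH1 rose by 1.56 ± 0.25 and the light chain gene FTL by 0.80 ± 0.23. Among 16 ferroptosis regulators 7 rose and 1 fell (7 and 1 adjusted over the list alone), with SLC3A2 at 1.31 ± 0.10 and POR at 1.28 ± 0.11 (camera adjusted p = 0.0318; adjusted p = 0.182 with an estimated correlation). GPX4, the lipid peroxide-reducing peroxidase, fell from 157 ± 31.0 to 89.1 ± 12.6 FPKM. The call of the ferroptosis regulators ended without control replicate 3 (camera adjusted p = 0.0591), and without it and lactoferrin replicate 1 together (0.101).

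Of the 24 G2 and M phase genes 20 fell and 0 rose (21 and 0 adjusted over the list alone), with a median log2 fold change of -0.79 and HMMR at -2.52 ± 0.27 (camera adjusted p = 2.46e-10; adjusted p = 0.15 with an estimated correlation). In the list of epithelial-mesenchymal transition and matrix genes 14 of 28 fell and 3 rose (16 and 6 adjusted over the list alone; camera adjusted p = 0.00299; adjusted p = 0.354 with an estimated correlation). Its members with the smallest adjusted p went the other way: MMP1, above, and MMP3, stromelysin 1, which was listed at 0 in the 3 control libraries and at 2.15 ± 0.359 FPKM with PM2.5. Among 8 squamous and keratinocyte markers 4 fell and 0 rose (5 and 1 adjusted over the list alone), with the plakoglobin gene JUP at -1.37 ± 0.09 and KRT80 at -1.06 ± 0.08 (camera adjusted p = 0.0254; adjusted p = 0.15 with an estimated correlation). The ribosomal protein list had 4 of 30 genes lower and 0 higher (0 and 0 adjusted over the list alone), with RPL3 at -0.55 ± 0.16 (camera adjusted p = 0.000217; adjusted p = 0.578 with an estimated correlation). Nuclear-encoded OXPHOS genes had 5 of 30 lower and 0 higher (4 and 0 adjusted over the list alone), with COX4I1 at -0.58 ± 0.15 and NDUFA2 at -0.74 ± 0.20 (camera adjusted p = 0.0482; adjusted p = 0.657 with an estimated correlation). The mean log2 level of the ribosomal list ranged from -0.26 to 0.265 between the control libraries alone. The call of the nuclear-encoded OXPHOS list ended without control replicate 1 (camera adjusted p = 0.255, median -0.06 against -0.15), control replicate 2 (0.0506), PM2.5 replicate 2 (0.0859), PM2.5 replicate 3 (0.124) or lactoferrin replicate 2 (0.0567), and its median was -0.24 without control replicate 3. It also ended with upper-quartile factors (0.059), without scaling (0.0592), under the stricter filter (0.0629) and after the length and GC trend was removed (0.0624). The call of the squamous and keratinocyte markers ended with no filter on low values (camera adjusted p = 0.135, median -0.01 against -0.50), under the stricter filter (0.089) and without control replicate 3 and lactoferrin replicate 1 together (0.0543). The median of the cytosolic ribosomal proteins was -0.26 without control replicate 1, against -0.42.

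**Figure D2:**
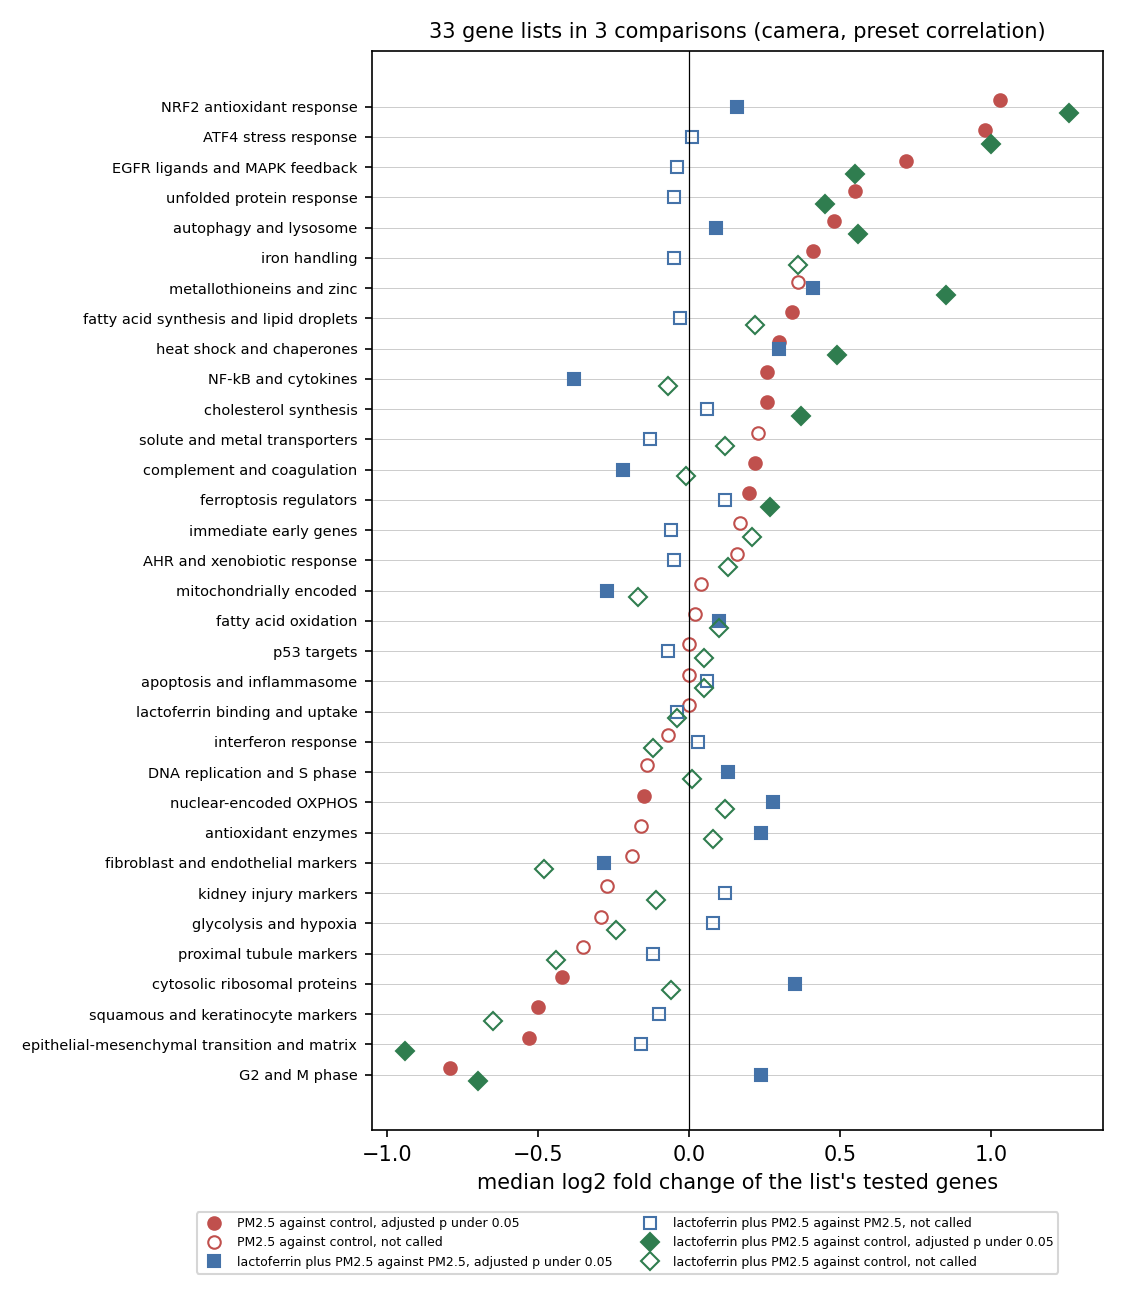
Median log2 fold change (horizontal axis) of the tested genes of each of 33 gene lists (vertical axis) in the 3 comparisons. Filled symbols mark lists with a camera adjusted p under 0.05 at the preset correlation and open symbols those without. The NF-kB and cytokine list lay at 0.26, -0.38 and -0.07, and the NRF2 list at 1.03, 0.16 and 1.26.

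At the preset correlation camera called 17 of 33 lists in this comparison, and with estimated correlations 0, the smallest adjusted p being 0.135. fry, which tests whether a list's genes move on balance in one direction, called 25. Those did not include the ribosomal protein list (fry adjusted p = 0.103) or the nuclear-encoded OXPHOS list (fry adjusted p = 0.303). Fold changes were on the log2(FPKM + 0.5) scale, which understates the change of genes with low values.

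The second comparison asked what lactoferrin pretreatment changed in cells exposed to PM2.5. No group had lactoferrin without PM2.5, so an effect of lactoferrin by itself cannot be told apart from a changed response to PM2.5. The NF-kB and cytokine list was lower: 23 of its 26 tested genes had negative log2 fold changes, with a median of -0.38. LCN2 (ENSG00000148346, GRCh38 chromosome 9, 128149071 to 128153455, plus strand) fell from 4.86 ± 0.395 to 1.97 ± 0.191 FPKM (SD, n = 3 each), a log2 fold change of -1.11 ± 0.10 (limma adjusted p = 0.00613), against 2.1 ± 0.131 FPKM in control. HSPA6, an inducible HSP70 gene, rose from 3.0 ± 0.150 to 6.54 ± 0.345 FPKM (1.01 ± 0.09, adjusted p = 0.00613). PDK4, a kinase that inhibits pyruvate dehydrogenase, rose by 0.71 ± 0.08 (adjusted p = 0.0206). The Notch ligand gene JAG1 (-0.96 ± 0.12, adjusted p = 0.0333), the lectin receptor gene CLEC4E (-0.84 ± 0.09, adjusted p = 0.0206) and the ubiquitin ligase gene RNF144B (-0.79 ± 0.09, adjusted p = 0.0206) fell.

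Those 6 genes and RPS27P4 were the 7 genes called, 3 higher and 4 lower. RPS27P4 (1.63 ± 0.19, adjusted p = 0.0206), a pseudogene that was chosen after its values were seen, can share reads with RPS27. At an unadjusted p under 0.05 there were 1764 genes where 723 would be expected by chance. The limma-voom fit of rebuilt fragments called 5 higher and 13 lower, of which 6 were among the 7. With no filter on low values 6 genes were called, 2 of them among the 7. From only the 6 libraries compared 4 were called, 3 of them among the 7. In the main fit without PM2.5 replicate 1, PM2.5 replicate 2 or lactoferrin replicate 2 the count was 0, and without PM2.5 replicate 3 it was 3. It was 4 without control replicate 1 or 2, 5 without lactoferrin replicate 1 or 3, and 10 without control replicate 3. The labels give 24 h of PM2.5 for one of the groups compared and 18 h for the other, and the series text gives 18 h for pretreated cells alone.

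In the NF-kB and cytokine list 1 of 26 genes fell and 0 rose (16 and 1 adjusted over the list alone). The camera adjusted p was 1.68e-12 at the preset correlation and 0.00503 with an estimated correlation, the single list of 33 called both ways. IL6 stood at 114 ± 11.9 FPKM with PM2.5 and 68.9 ± 1.18 FPKM with lactoferrin plus PM2.5 (-0.71 ± 0.10, limma adjusted p = 0.0654). CXCL8 stood at 235 ± 17.0 and 143 ± 22.6 FPKM (-0.72 ± 0.16, limma adjusted p = 0.215). Outside the list, the adhesion molecule gene VCAM1 stood at 2.95 ± 0.178 and 1.51 ± 0.334 FPKM (-0.78 ± 0.12, limma adjusted p = 0.072). Unlike IL6 and CXCL8, VCAM1 had been lowered by PM2.5 from 4.5 ± 0.315 FPKM in control (-0.58 ± 0.12, limma adjusted p = 0.0057). Its value with lactoferrin plus PM2.5 thus lay further from control. The mean log2 level of the list relative to control was 0.478, 0.413 and 0.45 in the PM2.5 libraries and 0.01, 0.038 and 0.044 in the lactoferrin libraries. That mean averages members that differed from control in both directions. With lactoferrin plus PM2.5, 7 members were higher than control and 9 lower, so a mean near control is not a return of each gene.

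**Figure D3:**
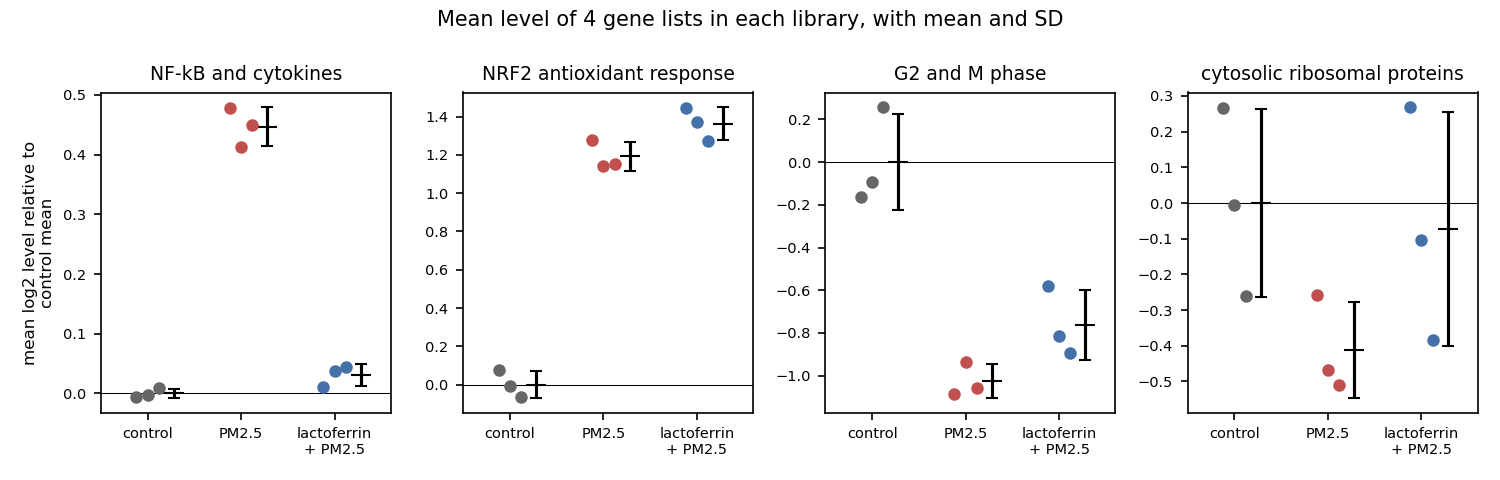
Mean log2 level of 4 gene lists relative to the control mean (vertical axes) in each of the 9 libraries, by group, with the group mean and SD (n = 3). For the NF-kB and cytokine list the lactoferrin libraries lay between 0.01 and 0.044 and the PM2.5 libraries between 0.413 and 0.478. With lactoferrin plus PM2.5, 7 members of that list were higher than control and 9 lower. For the ribosomal protein list lactoferrin replicate 1 lay at 0.269 and replicate 3 at -0.385.

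Of the 20 heat shock genes 20 had positive log2 fold changes and 1, HSPA6, rose (4 adjusted over the list alone; camera adjusted p = 6.05e-08; adjusted p = 0.297 with an estimated correlation). BAG3 in that list was at 0.32 ± 0.08. The NRF2 list had 19 of 23 positive values and 0 called (1 higher adjusted over the list alone), with HMOX1 at 832 ± 75.7 and 1400 ± 117 FPKM (0.76 ± 0.13, limma adjusted p = 0.0883) and NQO1 at 0.51 ± 0.15 (camera adjusted p = 0.00107; adjusted p = 0.437 with an estimated correlation). The autophagy and lysosome list had 20 of 27 positive and 0 called (1 higher and 1 lower adjusted over the list alone), with CTSL at 0.69 ± 0.12 and ULK1 at -0.46 ± 0.10 (camera adjusted p = 0.00957; adjusted p = 0.332 with an estimated correlation). In the fatty acid oxidation list PDK4 was the 1 gene of 17 that rose (1 adjusted over the list alone), beside ANGPTL4 at 0.40 ± 0.12 (camera adjusted p = 0.0192; adjusted p = 0.297 with an estimated correlation). Metallothionein and zinc genes had 9 of 11 positive and 0 called (0 adjusted over the list alone), with MT1A at 0.53 ± 0.21 and SLC39A10 at -0.50 ± 0.17 (camera adjusted p = 0.0379; adjusted p = 0.297 with an estimated correlation). Without lactoferrin replicate 1 the medians went from 0.30 to 0.19 for heat shock and chaperones, from 0.16 to 0.09 for the NRF2 antioxidant response, and from 0.41 to 0.23 for metallothioneins and zinc. The metallothioneins and zinc call ended without control replicate 3 (camera adjusted p = 0.0711), PM2.5 replicate 2 (0.0578), PM2.5 replicate 3 (0.0894) or lactoferrin replicate 2 (0.0571), or without control replicate 3 and lactoferrin replicate 1 together (0.112). That of fatty acid oxidation ended without lactoferrin replicate 3 (0.0538).

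The other lists called had no member past the test over all genes. Ribosomal protein genes had 30 of 30 positive values (0 adjusted over the list alone), a median of 0.35 and RPL5 at 0.32 ± 0.14 and RPL6 at 0.32 ± 0.14 (camera adjusted p = 4.43e-08; adjusted p = 0.535 with an estimated correlation). Nuclear-encoded OXPHOS genes had 30 of 30 positive (0 adjusted over the list alone), with COX6A1 at 0.50 ± 0.18 and COX5A at 0.35 ± 0.14 (camera adjusted p = 7.39e-08; adjusted p = 0.535 with an estimated correlation). Antioxidant enzymes had 22 of 23 positive (0 higher and 1 lower adjusted over the list alone), PRDX4 at 0.42 ± 0.14 and SOD2 at -0.42 ± 0.10 (camera adjusted p = 1.52e-05; adjusted p = 0.535 with an estimated correlation). G2 and M phase genes had 22 of 24 positive (0 adjusted over the list alone), with HMMR at 0.92 ± 0.27 and UBE2C at 0.39 ± 0.14 (camera adjusted p = 0.000131; adjusted p = 0.522 with an estimated correlation). DNA replication genes had 22 of 25 positive (0 adjusted over the list alone), with RRM2 at 0.22 ± 0.07 (camera adjusted p = 0.00121; adjusted p = 0.535 with an estimated correlation). Mitochondrially encoded genes had 12 of 13 negative (0 adjusted over the list alone), with MT-ND5 at -0.43 ± 0.20 and MT-ND6 at -0.45 ± 0.21 (camera adjusted p = 0.00632; adjusted p = 0.572 with an estimated correlation). Fibroblast and endothelial markers had 5 of 5 negative (1 lower adjusted over the list alone), LUM at -0.33 ± 0.09 and MCAM at -0.29 ± 0.12 (camera adjusted p = 0.0109; adjusted p = 0.297 with an estimated correlation). The complement and coagulation list had 12 of 16 negative (1 higher and 2 lower adjusted over the list alone), with C3 at -0.80 ± 0.16 (camera adjusted p = 0.0277; adjusted p = 0.572 with an estimated correlation). In total camera called 14 of 33 lists at the preset correlation, 1 with an estimated correlation, and fry called 5. Among lists called by camera, fry gave an adjusted p of 0.299 for cytosolic ribosomal proteins, 0.297 for nuclear-encoded OXPHOS and 0.299 for antioxidant enzymes. It gave 0.217 for G2 and M phase and for DNA replication, 0.387 for mitochondrially encoded genes and 0.299 for complement and coagulation. For the NRF2 list it gave 0.101 and for metallothioneins and zinc 0.0714. None of these lists was called by fry. Across genes, which are not independent replicates, the log2 fold change of this comparison had a Spearman correlation of -0.28 with transcript length. The deviation of lactoferrin replicate 1 from the gene means had one of -0.33, that of lactoferrin replicate 2 one of -0.18 and that of replicate 3 one of 0.1. For PM2.5 replicates 1, 2 and 3 it was -0.08, 0.19 and 0.15. Without lactoferrin replicate 1 the medians went from 0.35 to 0.16 for cytosolic ribosomal proteins, 0.28 to 0.13 for nuclear-encoded OXPHOS, and 0.24 to 0.13 for antioxidant enzymes. They went from 0.13 to 0.06 for DNA replication and S phase, and from -0.28 to -0.18 for fibroblast and endothelial markers. The call of the mitochondrially encoded list ended without PM2.5 replicate 1 (camera adjusted p = 0.239, median -0.11 against -0.27) or lactoferrin replicate 3 (0.156, median -0.18), or with no filter on low values (0.126). That of fibroblast and endothelial markers ended without lactoferrin replicate 3 (0.111) or with no filter (0.85, median 0.00). That of complement and coagulation ended without PM2.5 replicate 1 (0.0723) or lactoferrin replicate 1 (0.0599, median -0.14 against -0.22).

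Whether lactoferrin moved the PM2.5-responsive genes back was asked by setting both comparisons beside each other. LCN2 and CLEC4E rose with PM2.5 and fell with lactoferrin, and 1 gene, RPS27P4, fell and then rose, so 3 genes changed in opposite directions and 4 in the same direction. The opposite count was 5 without control replicate 3 and 1 without control replicate 1, PM2.5 replicate 3 or lactoferrin replicate 1. It was 0 without PM2.5 replicate 1, PM2.5 replicate 2 or lactoferrin replicate 2. Simulations that kept the PM2.5 effect and had no lactoferrin effect gave 0.14 ± 0.495 opposite genes (SD of 50 draws). They added residual noise to the observed group means, which already hold noise, so the PM2.5 effect they kept may be too large. Unchanged groups, in which PM2.5 has no effect to oppose, gave a mean of 0.02. Independent lists of those sizes would share 0.75 genes that rose and then fell and 0.49 that fell and then rose, against 2 and 1 observed. The covariance of the log2 fold changes was -0.020 over all tested genes, against -0.026 ± 0.015 (SD of 50 draws) for unchanged groups, a difference of 0.006. Of the genes changed by PM2.5, 51.5% had the opposite sign under lactoferrin, against 59.3% ± 10.6 in simulations that kept the PM2.5 effect and had no lactoferrin effect.

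The third comparison set lactoferrin plus PM2.5 against control. MMP1 rose from 7.19 ± 0.624 to 244 ± 11.7 FPKM (log2 fold change 4.96 ± 0.10), HMOX1 to 1400 ± 117 FPKM (4.77 ± 0.13) and ANGPTL4 to 49.2 ± 7.25 FPKM (4.73 ± 0.12). ATP6V0D2 (4.34 ± 0.14), THBD (4.19 ± 0.22), VGF (4.10 ± 0.19), HSPA6 (3.33 ± 0.09) and CSF2 (3.25 ± 0.14) followed. IGFBP3 fell by a log2 fold change of -4.27 ± 0.08, THBS1 of -3.85 ± 0.19 and TGFB2, a transforming growth factor gene, from 69.6 ± 8.83 to 8.51 ± 1.88 FPKM (-3.01 ± 0.19). NCKAP5, FILIP1L, LINC02274, ID3 and FGFR2 had values between -3.66 and -2.90. In total 2929 genes were higher and 2625 lower (limma adjusted p under 0.05).

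Of the 23 NRF2 targets 23 rose (23 adjusted over the list alone), with a median log2 fold change of 1.26 and GCLM at 1.45 ± 0.07 (camera adjusted p = 2.83e-13; adjusted p = 0.129 with an estimated correlation). Of the ATF4 targets 18 of 23 rose and 1 fell (19 and 1 adjusted over the list alone), with GDF15 at 2.76 ± 0.15 and TRIB3 at 2.35 ± 0.15 (camera adjusted p = 5.21e-09; adjusted p = 0.207 with an estimated correlation). The autophagy and lysosome list had 18 of 27 higher and 2 lower (20 and 2 adjusted over the list alone), with CTSL at 2.59 ± 0.12 and SQSTM1 at 2.13 ± 0.11 (camera adjusted p = 3.51e-06; adjusted p = 0.129 with an estimated correlation). Heat shock genes had 12 of 20 higher and 0 lower (15 and 0 adjusted over the list alone), with HSPA1B at 1.74 ± 0.10 (camera adjusted p = 4.26e-05; adjusted p = 0.278 with an estimated correlation). The unfolded protein response list had 12 of 21 higher (13 adjusted over the list alone), with HERPUD1 at 1.06 ± 0.09 and DNAJB9 at 1.15 ± 0.11 (camera adjusted p = 0.000277; adjusted p = 0.222 with an estimated correlation). Metallothionein and zinc genes had 7 of 11 higher and 1 lower (7 and 1 adjusted over the list alone), with SLC30A2 at 0.97 ± 0.14 and SLC39A10 at -1.84 ± 0.17 (camera adjusted p = 0.0338; adjusted p = 0.207 with an estimated correlation). Ferroptosis regulators had 7 of 16 higher and 1 lower (7 and 1 adjusted over the list alone), with POR at 1.68 ± 0.11 and SLC3A2 at 1.39 ± 0.10 (camera adjusted p = 0.00964; adjusted p = 0.207 with an estimated correlation). Cholesterol synthesis had 12 of 24 higher and 4 lower (14 and 4 adjusted over the list alone), with INSIG1 at 2.5 ± 0.07 and MSMO1 at 1.05 ± 0.09 (camera adjusted p = 0.0139; adjusted p = 0.207 with an estimated correlation). EGFR ligands and MAPK feedback genes had 13 of 22 higher and 5 lower (14 and 5 adjusted over the list alone), with DUSP6 at 2.31 ± 0.09 and PHLDA1 at 1.54 ± 0.07 (camera adjusted p = 0.00115; adjusted p = 0.417 with an estimated correlation). The call of the metallothioneins and zinc list ended without control replicate 2 (camera adjusted p = 0.0572) or lactoferrin replicate 1 (0.0518), or without control replicate 3 and lactoferrin replicate 1 together (0.0775), and that of cholesterol synthesis after the length and GC trend was removed (0.0524).

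Of the 24 G2 and M phase genes 16 fell and 0 rose (17 and 0 adjusted over the list alone), with KIF20A at -1.20 ± 0.10 and NUSAP1 at -0.70 ± 0.09 (camera adjusted p = 2.21e-06; adjusted p = 0.278 with an estimated correlation). Epithelial-mesenchymal transition and matrix genes had 17 of 28 lower and 5 higher (17 and 6 adjusted over the list alone; camera adjusted p = 0.00105; adjusted p = 0.294 with an estimated correlation). MMP3 was at 4.39 ± 0.218 FPKM, listed at 0 in control. The NF-kB and cytokine list had 7 of 26 genes higher and 9 lower (7 and 10 adjusted over the list alone), with a camera adjusted p of 0.64. IL6 (-0.11 ± 0.10, limma adjusted p = 0.412), CXCL8 (-0.18 ± 0.16, limma adjusted p = 0.405) and LCN2 (-0.11 ± 0.10, limma adjusted p = 0.42) did not pass the test against control. CSF2 (3.25 ± 0.14, limma adjusted p = 8.13e-07) and CXCL2 (0.86 ± 0.12, limma adjusted p = 0.000454) stayed higher than control. HAVCR1, the kidney injury molecule 1 gene, fell from 193 ± 32.6 to 63.8 ± 10.3 FPKM (-1.62 ± 0.16, limma adjusted p = 9.22e-05). In total camera called 11 of 33 lists at the preset correlation and 0 with an estimated correlation, the smallest adjusted p being 0.129, and fry called 25.

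Both comparisons against control called 2209 genes higher, 1857 lower and 2 in opposite directions. Independent lists of those sizes would share 548 and 431. The log2 fold changes had a correlation of 0.891 across genes and a covariance of 0.294, beside 0.455 ± 0.427 and 0.026 ± 0.015 for simulated unchanged groups sharing the control libraries (SD of 50 draws). Simulations that kept the PM2.5 effect and had no lactoferrin effect gave a correlation of 0.926 ± 0.029 and a covariance of 0.331 ± 0.03. They gave 4316 ± 560.0 shared calls, against 4066 observed. Residual noise was added there to the observed group means, which already hold noise. The simulated covariance and shared calls may therefore be too high, so the gap to the observed values cannot be read as an effect of lactoferrin. With 3 control libraries the controls could not be divided into 2 parts of at least 2 libraries. Part of the excess may come from the shared controls. In the unchanged groups, sharing the controls gave 0.1 ± 0.364 shared calls against 4066 observed, and a covariance of 0.026 against 0.294. These values argue against the shared controls as the whole of the excess.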

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

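The pseudocounts, the unscaled FPKM, the removal of the length and GC trend, the library weights and the fit without control replicate 3 and lactoferrin replicate 1 were chosen after seeing the data. Of the planned tests for counts, limma-voom was run on rebuilt fragments. The planned quasi-likelihood and Wald tests were not run, since the values are FPKM, and the planned prior count was not varied. The other planned settings were applied to the limma fit. Of the named genes called, 59 of 69 kept their call under every alternative for PM2.5 against control and 53 of 57 for lactoferrin plus PM2.5 against control, with 0 reversals, but 0 of 7 did for lactoferrin plus PM2.5 against PM2.5. A fold of at least 1.5 left 1302 genes higher and 1386 lower with PM2.5 and 1405 and 1551 with lactoferrin plus PM2.5 against control, by construction. For lactoferrin plus PM2.5 against PM2.5 the main 3 higher and 4 lower became 5 and 15 under the stricter filter, 5 and 13 with limma-voom, and 6 and 17 after the length and GC trend was removed. The counts were also 5 higher at a pseudocount of 1, 9 lower without control replicate 3 and lactoferrin replicate 1, and 2 lower from only the 6 libraries compared; the cause was not tested. With 1 library left out, the counts ranged from 0 to 3 higher and 0 to 7 lower there, from 1963 to 3074 and 1685 to 2797 with PM2.5, and from 2158 to 2815 and 1895 to 2608 with lactoferrin plus PM2.5 against control. Library weights, whose estimation did not converge and gave lactoferrin replicate 2 a weight of 29.33 beside 0.17 for replicate 1, called 4441 higher and 4255 lower with PM2.5, 3396 and 3024 for lactoferrin plus PM2.5 against PM2.5, and 5598 and 5406 against control; the cause was not tested. Genes changed in opposite directions numbered 3, and 6 under the stricter filter, 10 after the length and GC trend was removed, 1863 with library weights, 5 without control replicate 3 and lactoferrin replicate 1, 11 at an adjusted p under 0.10, and 0 to 5 with 1 library left out. The covariance difference of 0.006 lay between 0.004 and 0.020 with 1 library left out and stayed within the simulated SD of 0.015 of its value under the other alternatives.

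Lists called fell from 17, 14 and 11 to 0, 1 and 0 with an estimated correlation, and became 5 for lactoferrin plus PM2.5 against PM2.5 and 25 for lactoferrin plus PM2.5 against control with fry. With 1 library left out they ranged from 15 to 17, 12 to 14 and 11 to 12. Over 20 fits, the OXPHOS call with PM2.5 was lost in 10, that of fatty acid synthesis in 9, and those of ferroptosis and squamous markers in 3 each. Under lactoferrin against PM2.5 the metallothionein call was lost in 6, the mitochondrial in 4, the complement in 3 and the fibroblast in 2. The NF-kB and cytokine list kept its call in 20 of 20 other fits, with medians from -0.42 to -0.32. Named genes that changed sign were called neither as reported nor in the setting that changed the sign. TFRC with PM2.5 was at -0.01 with RLE factors, -0.02 with library weights and 0.00 from the 6 libraries compared, and between -0.05 and 0.04 with 1 library left out. In the other comparisons it was at 0.01 and 0.05 without control replicate 3 and lactoferrin replicate 1. HMGCS1 with PM2.5 was between -0.03 and 0.13 with 1 library left out, and under lactoferrin against PM2.5 at -0.04 after the trend was removed, -0.13 with library weights and from -0.05 to 0.11 with 1 library left out. ACSL4 was at -0.04 with library weights, HSPA5 at 0.05 without both libraries and from -0.20 to 0.03 with 1 left out, and TXNIP at -0.04 after the trend was removed and from -0.02 to 0.06 with 1 left out. FN1 against control was at 0.07 after the trend was removed, 0.06 with library weights, 0.23 without both libraries and from -0.41 to 0.07 with 1 left out; the cause of these changes was not tested.

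Replicate numbers were not taken to pair the libraries, since the labels give shared numbers but no shared culture, day or batch. Correlations of same-numbered residuals ranged from -0.07 to 0.18, and those of other pairs between groups from -0.18 to 0.14. As a hint from the data and not the design, 7 of 9 libraries correlated best with their own number. The replicate block gave 2910 higher and 2775 lower with PM2.5, 5 and 8 for lactoferrin plus PM2.5 against PM2.5, 3155 and 2863 against control, and 5 genes in opposite directions. Under the block camera called 15 lists with PM2.5 against 17, without ferroptosis regulators (camera adjusted p = 0.0517) and fatty acid synthesis and lipid droplets (0.0618). For lactoferrin plus PM2.5 against PM2.5 it called 16 against 14, with immediate early genes (camera adjusted p = 0.0478) and epithelial-mesenchymal transition and matrix (0.0192) added, and against control 11 as without the block. At this depth and with 3 libraries per group, the smallest simulated fold change was recovered for 4%, 4% and 10% of genes in the 3 comparisons.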

Other observations

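The test of the PM2.5 response as a whole was chosen after the result it bears on was seen, as were the fits with the length and GC trend removed.

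CYP1A1 and CYP1B1, targets of the aryl hydrocarbon receptor, rose with PM2.5 by log2 fold changes of 2.22 ± 0.10 and 2.36 ± 0.14. In that list 4 of 9 genes rose (4 adjusted over the list alone), although the list as a whole was not called (camera adjusted p = 0.112). CDKN1A, a p53 target, rose by 1.40 ± 0.12, while 9 of 22 p53 targets rose and 3 fell (9 and 5 adjusted over the list alone; camera adjusted p = 0.351). TXNIP, which binds thioredoxin, fell from 58.7 ± 5.44 to 14.2 ± 0.453 FPKM. Kidney injury markers went both ways: HAVCR1 fell from 193 ± 32.6 to 99.6 ± 13.9 FPKM while LCN2 rose. Of 19 markers 3 rose and 6 fell (5 and 8 adjusted over the list alone; camera adjusted p = 0.267). Of the 10 proximal tubule markers tested, from a list of 26, 3 rose and 5 fell (3 and 5 adjusted over the list alone, camera adjusted p = 0.342).

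The remaining lists were not called with PM2.5. Interferon response genes had 2 of 17 higher and 6 lower (4 and 6 adjusted over the list alone; camera adjusted p = 0.25). Glycolysis and hypoxia genes had 6 of 29 higher and 10 lower (6 and 10; camera adjusted p = 0.23), and immediate early genes 8 of 23 higher and 4 lower (9 and 4; camera adjusted p = 0.25). Apoptosis and inflammasome genes had 4 of 22 higher and 2 lower (4 and 2; camera adjusted p = 0.553). Solute and metal transporters had 7 of 19 higher and 2 lower (9 and 3; camera adjusted p = 0.143). Genes of lactoferrin binding and uptake had 3 of 11 higher and 0 lower (3 and 0; camera adjusted p = 0.311). Fatty acid oxidation genes had 6 of 17 higher and 3 lower (7 and 5; camera adjusted p = 0.342), and metallothionein and zinc genes 4 of 11 higher and 1 lower (5 and 1; camera adjusted p = 0.182). DNA replication genes had 0 of 25 higher and 6 lower (0 and 6; camera adjusted p = 0.141). Antioxidant enzymes had 3 of 23 higher and 3 lower (3 and 3; camera adjusted p = 0.859), and fibroblast and endothelial markers 2 of 5 higher and 2 lower (2 and 2; camera adjusted p = 0.401). Mitochondrially encoded genes had 0 of 13 called (0 over the list alone; camera adjusted p = 0.98).

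The NF-kB and cytokine list was lower with lactoferrin plus PM2.5 than with PM2.5. Without lactoferrin replicate 1 its median log2 fold change was -0.35 (camera adjusted p = 5.99e-15), and after the trend on transcript length and GC content was removed -0.32 (camera adjusted p = 2.04e-14), against -0.38 before, so neither accounts for the whole of it. A weaker response to PM2.5 as a whole would lower other induced lists too. The 39 NRF2 and ATF4 genes raised by PM2.5 did not show it, with a median log2 fold change of 0.13 (quartiles -0.01 and 0.22). They pool 2 lists that differed: over all tested members the median was 0.16 for NRF2 and 0.01 for ATF4. The NRF2 list was itself called higher under lactoferrin at the preset correlation (camera adjusted p = 0.00107). Such a rise could hide a weaker response, so the pooled median cannot exclude one. Other lists called higher with PM2.5 went both ways. Medians were -0.22 for complement and coagulation (12 of 16 negative), -0.05 for iron handling (13 of 18) and -0.04 for EGFR ligands and MAPK feedback (13 of 22). They were 0.30 for heat shock, 0.12 for ferroptosis regulators and 0.09 for autophagy and lysosome. A weaker response in part of the induced genes therefore stays open. A lower NF-kB response under lactoferrin is a hypothesis that stays open. So does an effect of lactoferrin that does not depend on PM2.5, since no group had lactoferrin alone. A shorter time in PM2.5, which the labels give for that group (18 h against 24 h), stays open as well and cannot be separated from lactoferrin.

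The ribosomal protein and nuclear-encoded OXPHOS lists were higher with lactoferrin plus PM2.5 than with PM2.5 at the preset correlation, with 0 members called and adjusted p = 0.535 with an estimated correlation (limma camera) for each. After the length and GC trend was removed the larger of their medians was 0.28, against 0.35 before, so that trend does not account for the whole shift. Without lactoferrin replicate 1 it was 0.16, narrowly under the bound set beforehand for that library carrying most of the shift. The lists stayed called at the preset correlation (camera adjusted p = 0.000307). The ribosomal level also fell from replicate 1 to replicate 3 in every group. It went from 0.265 to -0.26 in control, from -0.257 to -0.51 with PM2.5 and from 0.269 to -0.385 with lactoferrin plus PM2.5. Leaving out lactoferrin replicate 1 while PM2.5 replicate 1 stayed therefore cannot decide how much of the shift that library carries.

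The G2 and M phase list was lower with PM2.5 than in control at the preset correlation, and camera gave an adjusted p = 0.15 with an estimated correlation. Its median was -0.81 (camera adjusted p = 2.5e-10) after the length and GC trend was removed and -0.80 (camera adjusted p = 4.17e-10) without control replicate 3, against -0.79 before, so neither accounts for the whole of it. An effect of PM2.5 on these genes, the difference the design names, stays open as a hypothesis.

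Splits of the 6 libraries of each comparison number 10, too few for a share under 0.05. With PM2.5 against control the real split called 5076 genes and the highest other 0, with lactoferrin plus PM2.5 against PM2.5 7 and 1, and with lactoferrin plus PM2.5 against control 5554 and 1. In each, 1 split called as many genes, the real one. Every other split mixed the real groups, so a difference between those groups entered its residual spread and lowered its count. The low counts of the other splits are therefore no support for any cause.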
